A study of Mus musculus with 15 samples.

How the data were processed

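RNA from 15 samples of mouse myeloid cells was measured on a single-colour Affymetrix array, 1 array per sample, with biotin-labelled cRNA made from 6 ug of total RNA. The groups, of 3 arrays each, were G-CSF-mobilised spleen CD11b+CD34+ lineage-negative cells of wild-type mice with the title codes RB and GFW, the same kind of cells after 3 days with SCF and Flt3 ligand (GFE), the same kind of cells from mice labelled iNOS knockout (GFK), and bone marrow cells cultured with IL-13, GM-CSF and G-CSF (MDSC). Monocytes and monocyte progenitors of untreated mice, which the study also describes, were not analysed here.

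The authors made the values with RMA in the oligo package, which corrects background, normalises quantiles across arrays and summarises probe sets. Per the labels and the values, the deposited unit is log2, not centred per gene. The versions of oligo and of RMA, and the genome build behind the array annotation, are not given in the sources used here, so no coordinates are printed. Values ran from 2.21 to 14.07 over 41345 probes, and no 2 arrays were identical. The sorted values of an array lay at most 0.321 and at the median 0.0593 log2 from the mean of the sorted arrays.

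Of the probes, 23521 were listed with 1 gene symbol, 1814 with several and 16010 with none, and the first kind was used. Of these, 23328 matched the RefSeq table of GRCm38.p6 by gene identifier, which was used for names and chromosomes, and 0 symbols needed an update. They covered 22180 genes, 1082 of them with more than 1 probe, for which the probe with the highest mean over all arrays was taken. A gene was kept if its value lay above the 40th percentile of its array (5.34 to 5.58 log2) on at least 3 arrays, which kept 14822 and removed 7358. Where the mean of the lower group ranked under the 40th percentile of probes, the difference is given as a lower bound, which holds for 5 of the 56 called genes named for arrays labelled knockout minus GFW, 13 of 58 for culture, 15 of 52 for MDSC and 15 of 43 for RB minus GFW.

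The values of all 15 arrays were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, a mean per group, 10 residual and 5.33 prior degrees of freedom). Adjusted p values are Benjamini-Hochberg values of limma's moderated test over all genes tested, 2-sided, and a gene was called at an adjusted p under 0.05. The comparisons were arrays labelled knockout minus GFW, cultured minus GFW, MDSC minus the mean of RB and GFW and minus each, and RB minus GFW. Standard errors are limma's. These comparisons share arrays, so they are not independent. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used to prepare the values and for figures, and Fisher's exact test was run in R.

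The gene lists, the comparisons named above, their tests and the alternatives were fixed before the data were examined. The comparison of the arrays labelled knockout with RB, the overlap of MDSC minus RB with cultured minus GFW, and the tests of technical explanations other than those on plasma cell genes and on other splits were chosen after the values were seen. The 27 lists were haematopoietic progenitor, primary granule, neutrophil and later granule, monocyte, macrophage, MHC class II presentation, dendritic cell, mast cell and basophil, eosinophil, erythroid, megakaryocyte and platelet, B cell, T cell and NK cell, suppressor and regulatory, nitric oxide and arginine metabolism, IL-4 and IL-13 response, inflammatory cytokine and NF-kB, type I interferon response, interferon gamma response, co-stimulatory and co-inhibitory ligand, mitosis and DNA replication, glycolysis and hypoxia, cholesterol synthesis, immediate early and dissociation, amino acid and integrated stress response, NADPH oxidase, and neighbours of Nos2 on chromosome 11. Of their 426 entries, 37 had no probe of a single gene. Some genes belong to several lists, such as Nos2, Arg1, Cybb, Cd274 and Socs1. Each list was tested against all other genes with camera (preset correlation 0.01, adjusted over the lists of a comparison) and, as alternatives, with a correlation estimated per list and with fry. List members called are given over all genes and adjusted over the list alone.

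Genes were named by a fixed rule: Nos2; per comparison, the 10 higher and 10 lower genes with the largest log2 difference among those called in which every array of one group lay above every array of the other (which 3 arrays against 3 do by chance for 10% of splits), for MDSC among those called against each set alone; and per list, 2 to 4 called members with the largest difference and any further member with its value. Predicted gene models and immunoglobulin or T cell receptor segments were counted and not named, apart from Ighm of the B cell list, Iglv1 of the plasma cell genes, and Ighg3. The last, with Jchain, Mzb1, Pou2af1, Marco and Fcna, was chosen after its values were seen.

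The fit was tested on simulated data with 14822 genes and the spread of these arrays. For arrays labelled knockout minus GFW, 31.3% of genes shifted by 0.5 log2 were called, 88.1% of those shifted by 1 and all of those shifted by 2, and 10 unshifted genes were called. For culture the shares were 35.8% and 86.6%, for MDSC 52.2% and 92.5%, and for RB minus GFW 23.9% and 92.5%, with 9, 10 and 8 unshifted genes called. A shifted list passed in all 4 comparisons, and 0 other lists did. The simulated genes varied independently of each other and few were shifted. These results therefore do not cover lists of correlated genes or comparisons in which most genes are called.

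Alternatives were no filter, a filter at the 60th percentile, the mean of all probes of a gene, each array minus its median, and quantile normalisation again. Others were eBayes with a trend and a robust fit, array weights, only the arrays compared, at least a 2-fold difference, and limma's treat against 1.5-fold. The rest were the replicate number as a block, both wild-type sets as 1 group, and each array left out in turn. The block was fitted to the GFW, GFE and GFK arrays alone. For MDSC, the title prefix as a random block and each set alone were used too. The prefix is the first part of the title, which GFW, GFE and GFK arrays share, while RB and MDSC arrays each have their own. The random block fit gave RB and GFW 1 mean. The number of arrays limits the precision.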

Results

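Gene expression was measured on 15 single-colour arrays of mouse myeloid cells, in 5 groups of 3 arrays. Cells of 4 groups came from the spleens of mice given G-CSF, a growth factor that mobilises progenitors and myeloid cells. They were sorted for CD11b and CD34 after removal of cells with T cell, B cell, erythroid or Ly6G markers. Of these, 2 groups carry the same wild-type labels and differ in the code of their titles, RB or GFW. The arrays coded GFE hold such cells kept for 3 days in a medium with SCF and Flt3 ligand, and the arrays coded GFK are labelled iNOS knockout. The remaining group, MDSC, holds Ly6C+CD11b+ suppressor cells grown from marrow with IL-13, GM-CSF and G-CSF. The first part of the titles, the prefix, is the same for GFW, GFE and GFK arrays, and RB and MDSC arrays each have their own. Values are log2 RMA signals, and 14822 genes were tested. The array medians lay between 5.52 and 5.71 log2. The 3 arrays per group limit the precision, and since the labels do not say that replicates are separate mice, the p values measure the spread between these samples, which may be technical.

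Nos2, which encodes the inducible nitric oxide synthase (iNOS), was not lower on the arrays labelled iNOS knockout. Its signal there was 8.84, 8.91 and 8.92 (8.89 ± 0.05, SD, n = 3), against 8.09, 8.32 and 8.43 on the GFW arrays (8.28 ± 0.17). It was 5.80, 6.21 and 5.94 on the RB arrays, 6.57, 6.68 and 6.64 after culture, and 6.14, 6.17 and 6.26 on the MDSC arrays. The arrays labelled knockout minus GFW differed by 0.61 log2 (SE 0.12, adjusted p = 0.0125), with all 3 arrays above all 3 GFW arrays. This call was lost without GFK replicate 3 (adjusted p = 0.0539), without GFW replicate 1 (0.0587) and where only the 6 arrays compared entered the fit (0.0960). Its adjusted p ran from 0.0086 to 1 over the alternatives. Which exons the Nos2 probe set reads is not known here, so the signal does not tell a full transcript from a shortened one. Among 35 genes listed in advance as neighbours of Nos2 on chromosome 11, none was called (0 adjusted over the list alone, median -0.05, camera adjusted p = 0.491). Their distance from Nos2 was not checked. Of the 239 calls, 25 lay on chromosome 11, which holds 1246 of the 14822 genes (Fisher's exact test, 2-sided p = 0.24).

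The 2 wild-type sets were compared to see how far arrays with the same labels differ. The RB arrays held more monocyte transcripts. The matrix protein fibronectin (Fn1) was at least 108-fold higher than on the GFW arrays (6.75 log2, SE 0.13, adjusted p = 5.25e-15), coagulation factor F13a1 66.7-fold and thrombospondin (Thbs1) at least 55.8-fold. Ms4a8a was higher by 5.31 log2, Ms4a4a by 4.73, Nxpe4 4.71, the scavenger receptor Msr1 4.64, versican (Vcan) 4.52 and Ms4a4c 4.33. The GFW arrays held more neutrophil transcripts. Steap4 was lower in RB by 6.85 log2, Prok2 by 6.56, the stefins Stfa1 by 6.45 and Stfa3 by 6.35, Cstdc4 by 6.16, Saa3 by 6.12, Il1f9 by 6.07 and Chil1 by 5.80. The lower mean ranked under the 40th percentile of probes, near background, for Fn1, Thbs1, Ms4a8a, Ms4a4a, Nxpe4, Msr1, Vcan, Steap4, Prok2 and Stfa3, so their differences are lower bounds. Ly6g, a neutrophil surface antigen used to remove cells in the sort, stood at 12.19 ± 0.03 (SD, n = 3) on the GFW and 6.28 ± 0.10 on the RB arrays. Kit, the SCF receptor of progenitors, stood at 11.43 ± 0.08 and 5.52 ± 0.49. Cd34 was 7.19 ± 0.20 on the GFW and 5.92 ± 0.11 on the RB arrays (-1.27, adjusted p = 7.19e-06).

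**Figure D1:**
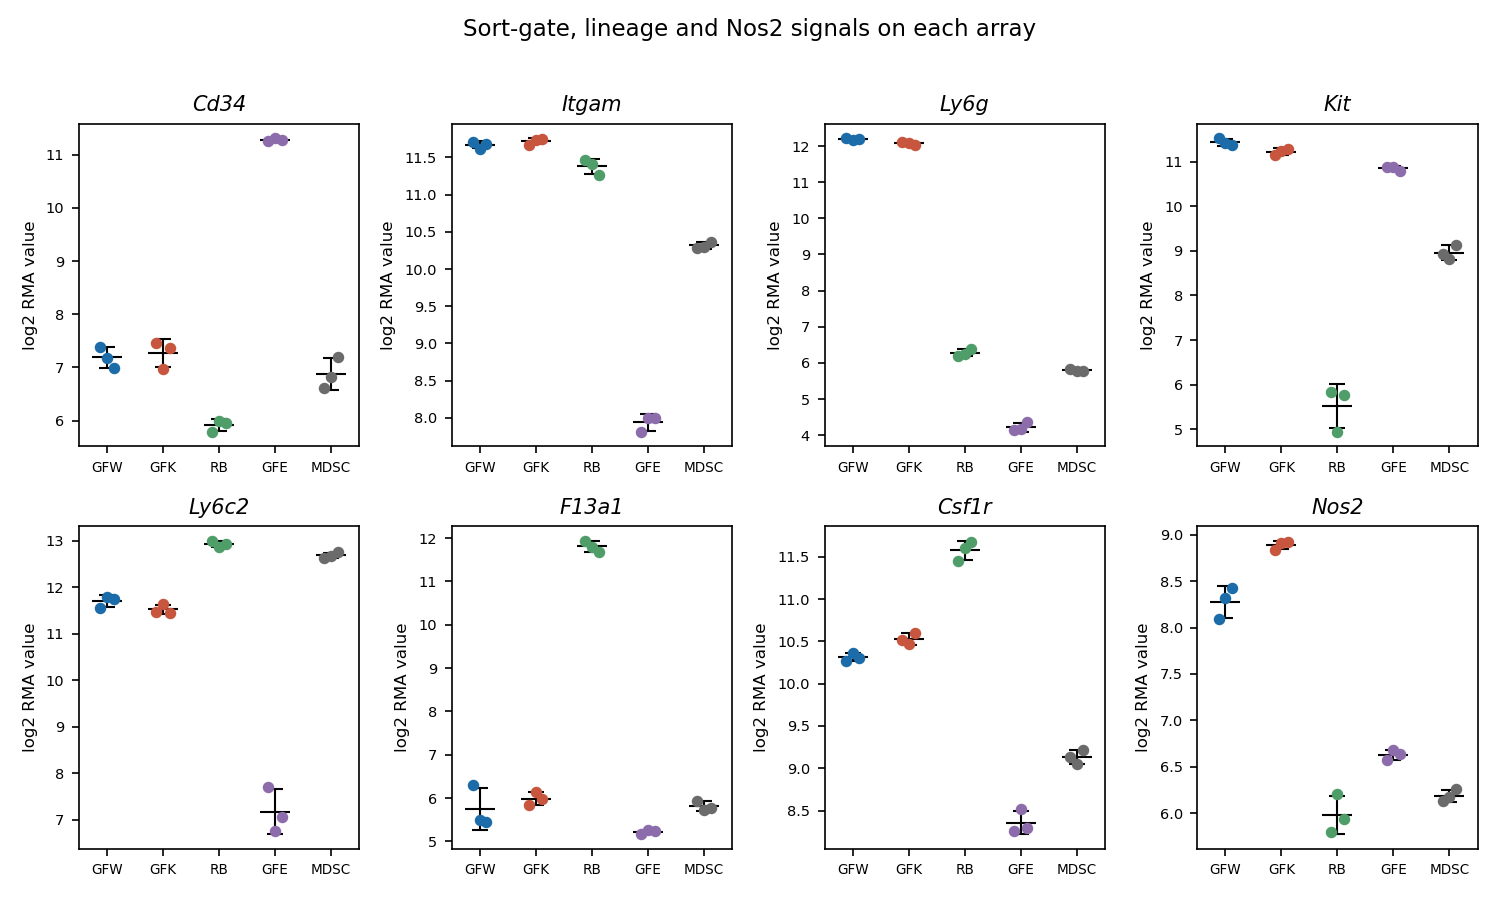
Log2 RMA signal of the sort markers Cd34, Itgam (CD11b) and Ly6g, of Kit, the monocyte genes Ly6c2, F13a1 and Csf1r, and Nos2, in the GFW and RB wild-type sets, GFK (arrays labelled iNOS knockout), GFE (cultured) and MDSC; points are arrays, dashes means and bars SD (n = 3). Ly6g lies near 12.19 on GFW and 6.28 on RB arrays, which carry the same labels.

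Of the gene lists, the monocyte list was higher in RB, with 13 of 16 members called higher and 1 lower (median 1.74, camera adjusted p = 1.39e-08): F13a1, Ace (4.71), Ccr2 (3.13), Csf1r (1.26) and Ly6c2 (1.24) rose, and Itgam fell by 0.29. The neutrophil and later granule list was lower (2 of 18 higher, 14 lower, median -1.37, adjusted p = 1.29e-06), with Ly6g -5.91, Mmp9 -4.87, Cxcr2 -4.80 and Retnlg -4.01, while the granule genes Camp (2.42) and Fcnb (1.61) were higher in RB. These 2 calls hold with an estimated correlation (0.00254 and 0.0136). A further 8 lists were called lower in RB with the preset correlation alone. With an estimated correlation the adjusted p was 0.088 for 6 of them. These were the progenitor list (2 higher and 13 lower of 18, median -0.69, Adgrl4 -2.13 but Cd93 2.26), the B cell list (6 of 8 lower, median -0.94, Ms4a1 -1.74) and the erythroid list (4 of 6 lower, median -0.71, Car1 -1.86). The others were the T and NK cell list (5 of 7 lower, median -0.73, Klrd1 -1.97), the stress response list (2 higher and 8 lower of 12, median -0.43, Asns -1.82) and the glycolysis list (1 higher and 6 lower of 14, median -0.33, Egln3 -3.12). It was 0.0989 for the eosinophil list (3 of 7 lower, -0.56, Siglecf -3.14) and 0.151 for the immediate early list (4 and 11 of 17, -0.66, Egr1 -1.98 and Klf2 -1.45 but Hspa1b 2.79). Adjusted over the list alone, the lower counts were 14 for progenitor, 5 for erythroid and 9 for stress response genes, and the others were the same. The differences of Fcnb, Adgrl4, Ms4a1, Egln3 and Car1 are lower bounds too. Macrophage genes (9 higher, 5 lower of 18, median 0.32, adjusted p = 0.102) and type I interferon genes (5 higher, 3 lower of 11, adjusted over the list alone 5 and 4, adjusted p = 0.965) did not pass. In the latter the median was 0.39 and the mean -0.01. Median and mean differed in sign also for the inflammatory (0.10 and -0.10), co-stimulatory (-0.09 and 0.23) and dendritic cell lists (-0.0019 and 0.17), which did not pass (0.965, 0.937 and 0.587). Of the arginases, Arg2 was lower in RB (-3.51).

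Over all genes, 3831 were higher and 3929 lower in RB (1256 and 739 by at least 2-fold). With each array minus its median the split was 3099 and 5635, and the median of all genes moved from -0.06 to -0.20. That scaling ended the calls of the eosinophil, erythroid, T and NK cell, glycolysis, immediate early and stress response lists. The Itgam call was lost without RB replicate 3 or GFW replicate 1 (adjusted p up to 0.0661). The eosinophil call was lost without RB replicate 2 (0.0521) or GFW replicate 2 (0.0609), the glycolysis call without RB replicate 2 (0.0716) or GFW replicate 1 (0.0525), and the immediate early call without RB replicate 2 (0.0878). The title code and the set are the same split, so no fit separates a difference between runs from one between cells.

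The arrays labelled iNOS knockout were compared with the GFW arrays to ask which transcripts differ in mobilised cells labelled as lacking iNOS. Genes induced by interferon gamma and inflammatory cytokines were higher on them. Gbp5, a guanylate binding protein, was 4.61-fold higher (8.84 ± 0.08 against 6.63 ± 0.20, SD, n = 3, adjusted p = 2.28e-06), the T cell chemokine Cxcl9 3.25-fold (adjusted p = 0.00704), and the cytokine Tnf 3.67-fold (10.38 ± 0.14 against 8.51 ± 0.21, adjusted p = 1.17e-06). Cd274, which encodes the inhibitory ligand PD-L1, was 2.86-fold higher (9.85 ± 0.12 against 8.33 ± 0.04, adjusted p = 2.45e-04). The fatty acid binding protein Fabp4 had the largest difference (at least 3.58 log2, SE 0.23, adjusted p = 7.02e-07). It stood at 7.68 on the arrays labelled knockout and 7.73 on RB arrays, and at 4.10 on GFW arrays, percentile 12.3 of probes and near background. The other higher genes under the naming rule were Gbp8 (2.25), Csta2 (2.04), the macrophage protein Cd5l (1.66), Cpne8 (1.59), the B cell receptor component Cd79a (1.58) and the adenylate cyclase Adcy4 (1.54). The lower genes were Prr11 (-1.08), the double-stranded RNA receptor Tlr3 (-1.02), Trrap (-0.94), Arsb (-0.89), Tcea2 (-0.80), Med31 (-0.77), Ftsj1 (-0.77), Mpv17l2 (-0.71), the pyruvate carrier Mpc1 (-0.70) and Plekho1 (-0.66).

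**Figure D2:**
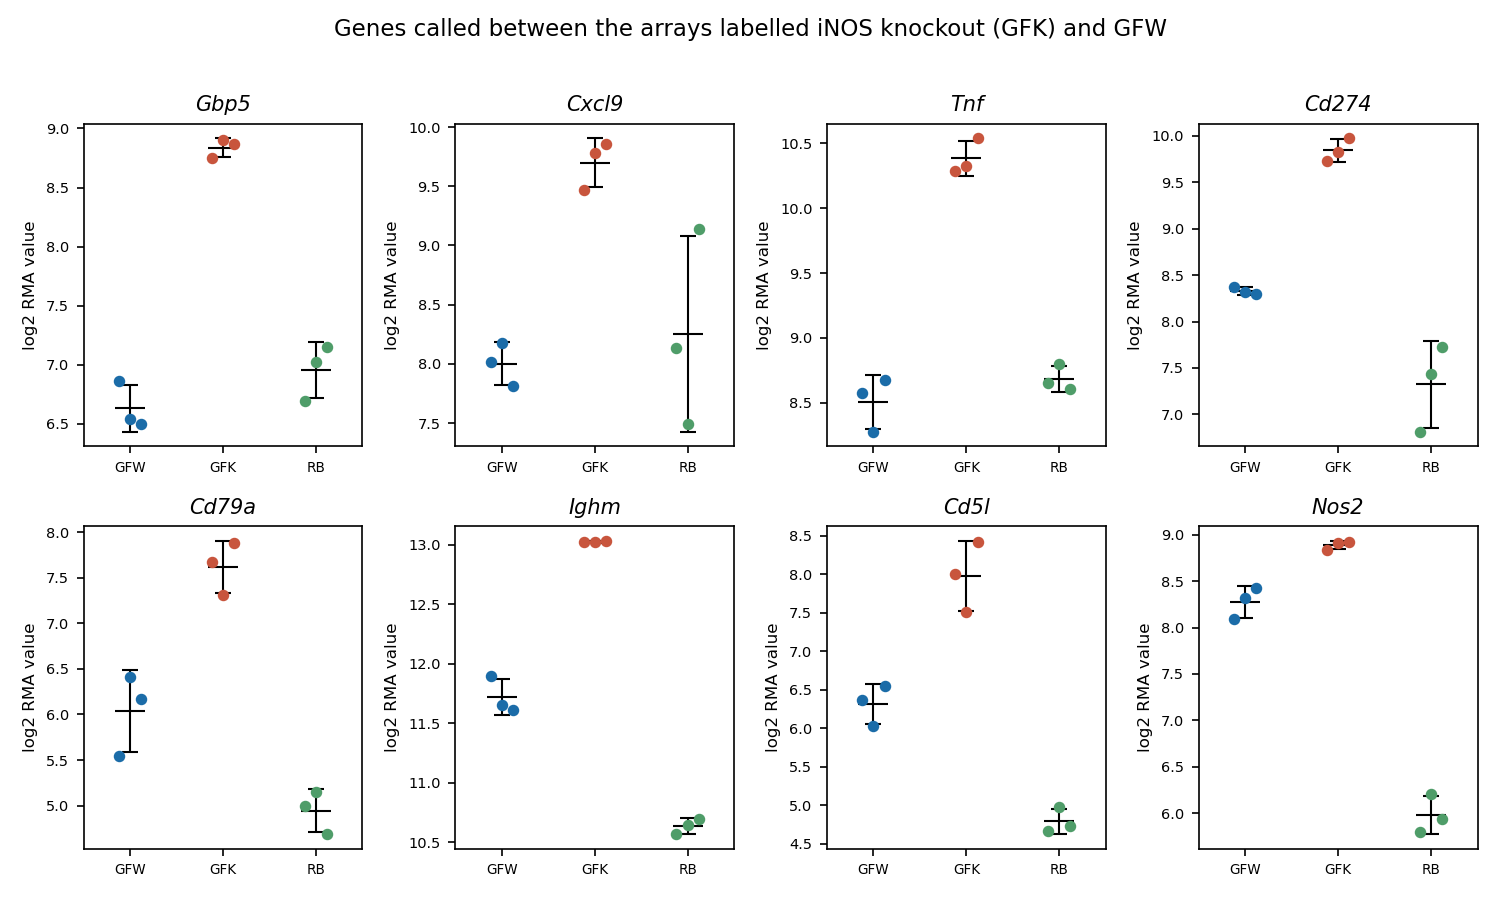
Log2 RMA signal of interferon, cytokine, checkpoint, B cell and macrophage genes and Nos2 in GFW, GFK (arrays labelled iNOS knockout) and RB; points are arrays, dashes means and bars SD (n = 3). Every GFK array lies above every GFW array for each gene, and the mean of Gbp5 is 8.84 on GFK and 6.63 on GFW arrays.

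In the interferon gamma list 10 of 13 members were higher and none lower (11 adjusted over the list alone, median 1.06, camera adjusted p = 1.89e-22): beside Gbp5 and Cxcl9 these included Cxcl10 (1.51), the immunity-related GTPases Iigp1 (1.48), Igtp (1.17) and Irgm1 (1.07). The others were Gbp3 (1.06), the transcription factor Irf1 (0.79), the cytokine signal inhibitor Socs1 (0.77) and Irgm2 (0.70). The antigen processing genes Tap1 (0.30), Psmb9 (0.22) and Psmb8 (0.13) were not called. The type I interferon list did not pass (median -0.09, adjusted p = 0.666), with Zbp1 (0.67) higher and Ifit1 (-0.61) lower of 11, both also adjusted over the list alone. In the inflammatory list 7 of 16 were higher (9 adjusted over the list alone, median 0.47, adjusted p = 1.45e-13), among them Tnf, Il1a (1.36), the chemokine Ccl3 (1.15) and the NF-kB inhibitor Tnfaip3 (0.95), whereas Il1b (-0.06) and Il6 (0.04) were not called. In the suppressor list 5 of 17 were higher (5 higher and 1 lower adjusted over the list alone, median 0.06, adjusted p = 0.00126): Cd274, Il10 (0.92), the NADPH oxidase subunit Cybb (0.68), Nos2 and Hmox1 (0.54). The arginase Arg1 was not called (0.05). The GFW means of Iigp1, Il1a and Il10 ranked under the 40th percentile, so their differences are lower bounds. Some of these calls were lost with single arrays left out. Cxcl10 and Nos2 were lost without GFK replicate 3 or GFW replicate 1 (adjusted p up to 0.0592 and 0.0587), and Iigp1 without these or GFW replicate 2 (up to 0.115). Il1a was lost without GFK replicate 2 or 3 or GFW replicate 1 or 3 (up to 0.121), and Il10 without GFK replicate 2 or any GFW array (up to 0.0961). Socs1 was lost without any array but GFK replicate 3 (up to 0.179), Hmox1 without any but GFK replicate 2 (up to 0.107), and Ifit1 without any of the 6 (up to 0.127).

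Markers of other cell types moved beside these groups. B cell genes passed (2 of 8 higher, 3 adjusted over the list alone, median 0.27, adjusted p = 1.28e-04), with Cd79a and the immunoglobulin heavy chain Ighm (1.30) called and Ms4a1 (0.20) and Pax5 (0.02) not. Macrophage genes passed (2 of 18 higher, 7 adjusted over the list alone, median 0.38, adjusted p = 2.97e-06), with Maf (0.96) and the complement gene C1qb (0.84) called, and Cd68 (-0.06), Apoe (0.03) and the mannose receptor Mrc1 (0.80) not. Monocyte genes passed (4 of 16 higher, adjusted over the list alone 7 higher and 2 lower, median 0.23, adjusted p = 1.34e-04): Ace (0.88), Treml4 (0.74), Spn (0.71) and Nr4a1 (0.66), which mark the patrolling, Ly6C-low type of monocyte, were higher, and Ccr2 (-0.69) and Ly6c2 (-0.17), which mark the classical type, were not called. Further genes chosen after their values were seen were the antibody genes Ighg3 (at least 2.47, with GFW at percentile 24.2), Pou2af1 (1.24), Jchain (1.12) and Mzb1 (1.07), and the macrophage receptors Marco (1.45) and Fcna (0.84), all called higher. Without single arrays the calls of Maf, C1qb, Treml4, Jchain, Mzb1 and Pou2af1 were lost in at least 1 fit, with each of the 6 arrays ending at least 2 of them and an adjusted p of at most 0.139 (C1qb).

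The interferon gamma, inflammatory, macrophage, B cell, monocyte and suppressor calls hold with an estimated correlation (adjusted p = 0.00337, 0.0084, 0.0146, 0.019, 0.0146 and 0.0425) and with each array left out. With both wild-type sets as the comparison, the macrophage call was lost (mean 0.097, adjusted p = 0.112) and the monocyte list turned in direction (mean -0.76, adjusted p = 0.0828). A further 3 lists were called with the preset correlation alone. The IL-4 and IL-13 list had 1 of 15 genes higher (4 adjusted over the list alone, median 0.05, adjusted p = 0.0435, and 0.256 with an estimated correlation). The progenitor list had 2 of 18 higher, Adgrl4 (0.77) and Hlf (0.50) (3 adjusted over the list alone, median 0.08, 0.0459 and 0.121). The eosinophil list had 1 of 7 higher, the granule protein Prg2 (1.47) (2 higher and 1 lower adjusted over the list alone, median 0.36, 0.0466 and 0.121). The progenitor call was lost without GFK replicate 1 (0.0819) or 3 (0.147) or GFW replicate 2 (0.0647) or 3 (0.0718). The eosinophil call was lost without GFK 1 (0.0534) or 2 (0.138) or GFW 1 (0.133) or 2 (0.0647), and the IL-4 and IL-13 call without GFK 1 (0.0699) or 2 (0.154) or GFW 1 (0.0687) or 2 (0.0992). Of their members, Adgrl4 (adjusted p up to 0.120), Hlf (0.168), Prg2 (0.0541) and Socs1 (0.179) lost their calls without single arrays. The gate genes Cd34 (0.08) and Ly6g (-0.11) were not called.

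Other lists did not pass on the arrays labelled knockout. No primary granule gene was called of 12 (1 higher adjusted over the list alone, median 0.04, adjusted p = 0.213). Of the MHC class II genes, 0 of 9 were called (0 adjusted over the list alone, median -0.26, adjusted p = 0.0532), with H2-Ab1 at -0.41. The mast cell and basophil list (0 of 5 and 0 adjusted over the list alone, median 0.28, adjusted p = 0.0532) and the megakaryocyte list (0 of 8 and 1, median 0.04, 0.666) did not pass. In the nitric oxide and arginine list Nos2 alone was called of 16 (1 higher and 1 lower adjusted over the list alone, median 0.05, adjusted p = 0.614). No mitosis gene was called of 24 (0 adjusted over the list alone, median -0.09, adjusted p = 0.0607), and in the NADPH oxidase list Cybb alone of 5 (2 adjusted over the list alone, median 0.06, 0.0607). For 3 lists the median lay below 0 while the mean lay above it and camera tested higher. In the dendritic cell list 0 of 14 genes were called (0 adjusted over the list alone, median -0.04, mean 0.02, adjusted p = 0.771). In the co-stimulatory list Cd274 alone was called of 14 (1 higher and 1 lower adjusted over the list alone, median -0.05, mean 0.15, adjusted p = 0.395). In the stress response list the cystine transporter Slc7a11 (1.31) was the single call of 12 (1 adjusted over the list alone, median -0.02, mean 0.10, adjusted p = 0.395).

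In all, 192 genes were higher and 47 lower on the arrays labelled knockout, 53 and 2 of them by at least 2-fold. Where only the 6 arrays compared entered the fit the counts were 72 and 2, and 29 of the 56 called genes followed over the alternatives lost their call, among them all of the lower genes above but Trrap. Tested against a 1.5-fold difference (treat), 14 were higher and 0 lower, and 47 of the 56 lost their call, Cxcl9 (0.503) and Cd79a (0.137) among them. The higher count was 102 without GFK replicate 3 and 123 without GFW replicate 3. The lower count was 28, 27 and 31 without GFK replicates 1, 2 and 3, and 30 and 27 without GFW replicates 2 and 3. Of the 56 called genes, 31 kept their call with each array left out. The other 25 lost it in at least 1 fit, among them Gbp8 (up to 0.163), Tlr3 (0.0853), Tcea2 (0.182), Ftsj1 (0.0538), Mpv17l2 (0.0786), Mpc1 (0.169) and Plekho1 (0.0864). Without GFK replicates 1, 2 and 3 in turn 13, 15 and 18 calls were lost, and without GFW replicates 1, 2 and 3 in turn 18, 16 and 18. With both wild-type sets as the comparison, 49 were higher and 13 lower, and Tnfaip3 (-0.023), Cybb (-0.29), Ace (-1.48), Spn (-0.22), Nr4a1 (-0.20) and Ifit1 (0.31) turned in direction, as did the monocyte list. None of these genes was called in that fit (adjusted p from 0.448 to 0.982). A further 24 of the 56 genes kept direction and lost their call, among them Nos2 (1.76, adjusted p = 0.177), Fabp4 (1.77, 0.304), Cxcl10 (1.17, 0.121), Gbp3 (0.72, 0.167), Irgm2 (1.49, 0.108), Il1a (1.005, 0.179), Ccl3 (0.81, 0.0775) and Il10 (0.50, 0.329).

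Cells after 3 days of culture were compared with the GFW arrays, taken as their input. After culture neutrophil transcripts were lower and progenitor transcripts higher. Ly6g fell by at least 7.97 log2 (4.22 ± 0.12 against 12.19 ± 0.03, SD, n = 3, adjusted p = 1.23e-17), Stfa2l1 by 9.26, Cstdc4 by 8.91, the granule gene Retnlg by 8.84, Stfa1 by 7.70, Il1f9 by 7.56, Stfa3 by 7.51, Sirpb1c by 7.37, Saa3 by 7.29 and the chemokine receptor Cxcr2 by 7.17. Cd34 was 17.1-fold higher (11.28 ± 0.03 against 7.19 ± 0.20, adjusted p = 4.21e-12), and Itgam, which encodes CD11b, fell by 3.73. The largest rises were in the protease inhibitor relatives Ctla2b (5.57) and Ctla2a (4.44), Bex1 (4.99), the complement receptor C3ar1 (4.91), the replication fork protein Tipin (4.74), the metallothionein Mt2 (4.72), the adhesion receptor Adgrg1 (4.72), Mras (4.47), Cd69 (4.44) and the desaturase Fads2 (4.44). Cultured means ranked under the 40th percentile, near background, for Ly6g, Stfa2l1, Cstdc4, Retnlg, Stfa1, Il1f9, Stfa3 and Sirpb1c, as did GFW means for Ctla2b, Bex1, C3ar1, Tipin and Mras, so these differences are lower bounds.

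In the progenitor list 16 of 18 members rose (median 2.78, camera adjusted p = 1.69e-07), among them the kinase Cdk6 (4.30), Cd34 (4.10), Adgrl4 (4.06) and Sox4 (4.06), while Kit fell by 0.58 and Gfi1 (-0.08) was not called. Cholesterol synthesis genes rose (11 of 12, median 2.94, adjusted p = 7.39e-07), led by Sqle (4.39), Cyp51 (4.02) and Hmgcs1 (3.80), with Sc5d (0.04) not called. Stress response genes rose (10 of 12 higher, 1 lower, median 1.19, adjusted p = 8.74e-04), led by the serine and asparagine synthesis genes Psat1 (3.11) and Asns (2.24). Neutrophil genes fell (17 of 18, median -5.17, adjusted p = 6.07e-13), with S100a8 -5.25 and S100a9 -5.18, and Fcnb (-0.35) not called. Immediate early genes fell (16 of 17, median -2.57, adjusted p = 1.04e-10), with Fos -4.92, Klf2 -4.80 and Dusp1 -3.62, and Hspa1b (-0.12) not called. Monocyte genes fell (4 higher and 12 lower of 16, median -1.55, adjusted p = 0.00441), with Ly6c2 -4.52 and Csf1r -1.96 against Ms4a6c 3.11, and Spn was 4.01-fold higher. These 6 calls hold with an estimated correlation (adjusted p = 0.00298, 0.0119, 0.0153, 0.00161, 0.00161 and 0.0402). Sesn2, a stress response gene, fell by 0.44, a call lost without GFE replicate 3 or GFW replicate 2 or 3 (adjusted p up to 0.157).

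A further 6 calls held with the preset correlation alone. All 24 mitosis and replication genes rose (median 2.04, adjusted p = 3.11e-10, and 0.0654 with an estimated correlation), with Mcm6 3.22, Bub1 3.09 and Mki67 1.29. Genes of MHC class II fell (7 of 9, median -1.47, 0.00277 and 0.0633), with H2-Eb1 -2.77 and H2-Aa -2.51. Macrophage genes fell (2 higher and 12 lower of 18, median -0.90, 0.00462 and 0.083), with C1qb -2.90 and Vcam1 -2.72 but Lpl 3.94 higher. The other 3 were the NADPH oxidase (4 of 5 lower, median -1.15, 0.00919 and 0.083, Cybb -1.93, Ncf1 0.10 not called), suppressor (2 higher, 8 lower of 17, median -0.37, 0.0414 and 0.152) and type I interferon lists (7 of 11 lower, median -0.55, 0.0414 and 0.44). In the suppressor list Arg2 fell by 4.97, the ectonucleotidase Entpd1 by 3.71 and Nos2 by 1.65, and Lgals1 rose by 3.20. In the interferon list Oasl2 fell by 2.23 and Zbp1 by 1.80. Adjusted over the list alone, the counts of these 12 lists were the same. The suppressor call was lost without GFW replicate 3 (adjusted p = 0.0506) and, like the type I interferon call, with each array minus its median (0.0749 and 0.103). With both wild-type sets as input the suppressor call (0.131) and that of Nos2 (-0.50, adjusted p = 0.461) were lost.

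Among the lists that did not pass after culture, inflammatory cytokines had 4 higher and 8 lower of 16 (the same adjusted over the list alone, median -0.47, adjusted p = 0.164). In it the chemokine Ccl3 rose by 2.25 and Ccl2 fell by 5.06. B cell genes had 1 higher and 7 lower of 8 (the same adjusted over the list alone, median -0.74, 0.0678). Erythroid genes had 2 higher and 3 lower of 6 (4 lower adjusted over the list alone, 0.968), with a median of -0.35 and a test for lower but a mean of 0.62. For the megakaryocyte list the median was -0.03 and the mean 0.10 (0.968). In all, 5198 genes were higher and 4733 lower (2718 and 1324 by at least 2-fold). With each array minus its median the split was 3891 and 7694, so the share of calls that were higher went from 52.3% to 33.6%, and the median of all genes moved from -0.06 to -0.38. With both wild-type sets as input Kit (2.37, adjusted p = 0.166) and Sesn2 (0.35, 0.486) turned in direction and were not called. In that fit Ms4a6c (1.60, adjusted p = 0.0754) and Spn (1.08, 0.0546) lost their calls beside Nos2, and 2979 genes were lower.

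The MDSC arrays were compared with the mobilised cells, as both are described as regulatory or suppressor populations, using the mean of the 2 wild-type sets and then each set alone. MDSC held more transcripts of the IL-4 and IL-13 response, and fewer of the interferon gamma response, though against GFW alone these 2 list calls did not hold with an estimated correlation (adjusted p = 0.0783 and 0.0796). The chemokine Ccl17 was at least 88-fold higher (6.46 log2, SE 0.23, adjusted p = 3.1e-12) and Oasl2 at least 36.1-fold lower (-5.18 log2, SE 0.11, adjusted p = 2e-14). Oasl2 belongs to the type I interferon list, whose call did not hold with an estimated correlation (adjusted p = 0.0668). The proton pump subunit Atp6v0d2 was at least 134-fold higher, Gpnmb at least 58.2-fold and the elastase Mmp12 at least 41.5-fold. Higher as well were Fabp4 (5.57), Rnase2a (5.49), Ms4a3 (5.35), the desaturases Scd1 (5.31) and Fads2 (4.82), and Cyp11a1 (4.91). The cytokine Il1b was 69.8-fold lower (-6.13 log2, SE 0.14, adjusted p = 3.05e-14). Retnlg fell by 5.96, Slfn4 by 5.27, Rtp4 by 5.06, Klra2 by 4.77, Ifi204 by 4.71, Adam19 by 4.63, the nuclear receptor Nr4a1 by 4.54, and Oas2 by 4.95. All of these passed against each set alone. In at least 1 group on the lower side the mean ranked under the 40th percentile for Atp6v0d2, Ccl17, Gpnmb, Fabp4, Rnase2a, Mmp12, Scd1, Cyp11a1, Retnlg, Oasl2, Rtp4 and Adam19, and for Mgl2, Arg1 and Cxcl9 of the lists, so these differences are lower bounds. Nos2 in MDSC fell by 0.94 relative to the mean of both sets and by 2.09 relative to GFW, and differed by 0.21 from RB, which was not called (adjusted p = 0.160). The call against the mean of both sets was lost with 1 mean of all 6 wild-type arrays (0.180) and with the title prefix as a random block (0.339).

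All 24 mitosis and replication genes were higher in MDSC, against both sets as well (median 2.46, camera adjusted p = 2.87e-15), with Bub1 3.68 and Cdk1 3.46. Cholesterol synthesis genes were higher (12 of 12, 11 against both sets, median 1.86, adjusted p = 3.07e-08), with Fdps 3.85, Sqle 3.75 and Cyp51 3.13. Primary granule genes were higher (10 higher and 2 lower of 12, 9 and 2 against both sets, median 2.83, adjusted p = 2.15e-04), with the proteases Ctsg (4.37) and Elane (4.29) and myeloperoxidase Mpo (3.80), and Igsf6 -0.65. The IL-4 and IL-13 response list was higher (13 higher and 1 lower of 15, 10 and 1 against both sets, median 1.57, adjusted p = 1.33e-05), with Ccl17, Mrc1 (3.99), Tfec (3.91), Mgl2 (3.33) and Arg1 (1.08), while the receptor Il4ra fell by 1.73. Interferon gamma genes were lower (1 higher and 11 lower of 13, the same against both sets, median -1.98, adjusted p = 1.52e-06), with Cxcl9 -2.76, Irgm2 -2.68 and Gbp3 -2.32, but Socs1 1.57. Immediate early genes were lower (1 higher and 16 lower of 17, 15 lower against both sets, median -2.49, adjusted p = 7e-11), with Fos -4.17 and Dusp1 -3.60, but Egr2 1.05. Monocyte genes were lower (3 higher and 13 lower of 16, 9 lower against both sets, median -1.51, adjusted p = 1.94e-06), with Treml4 -3.78, F13a1 -2.96 and Csf1r -1.81, but Klf4 0.59. Against GFW alone this list did not pass (0.102) and F13a1 was 0.065, and against RB alone Klf4 was -0.60. These 7 calls hold with an estimated correlation (adjusted p = 0.0396, 0.00742, 0.0452, 0.0452, 0.0452, 0.003 and 0.00637). They hold so against RB alone, but against GFW alone only the cholesterol synthesis (0.0306) and immediate early (0.00795) calls do. There the adjusted p with an estimated correlation was 0.0750 for mitosis, 0.0796 for primary granule, 0.0783 for IL-4 and IL-13, 0.0796 for interferon gamma and 0.181 for monocyte genes. With the title prefix as a random block the calls of Igsf6 (0.113), Arg1 (0.127), Egr2 (0.164), F13a1 (0.182) and Klf4 (0.657) were lost.

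With the preset correlation alone, type I interferon genes were lower (11 of 11, 10 against both sets, median -2.26, adjusted p = 3.07e-08, and 0.0668 with an estimated correlation), with Irf7 -3.39 and Isg15 -3.23. B cell genes were lower (4 of 8, 2 against both sets, median -0.62, 0.0275 and 0.117), with Ighm -1.79 and Cd22 -1.20. The call of Cd22 was lost with the title prefix as a random block (adjusted p = 0.358). The B cell call was lost against RB alone (0.272) and with each array minus its median (0.0573). Adjusted over the list alone, the counts of these 9 lists were the same. The suppressor list did not pass (4 higher and 8 lower of 17, median -0.15, adjusted p = 0.167), nor did glycolysis genes (9 higher and 1 lower of 14, median 0.51, 0.0649). The neutrophil list had a median of 0.37 and a mean of -0.23 (10 higher, 7 lower of 18, tested lower, 0.97). The counts of these 3 lists were the same adjusted over the list alone. Median and mean also differed in sign for the macrophage (-0.25 and 0.32, tested lower), erythroid (-0.14 and 0.63), megakaryocyte (-0.03 and 0.33), nitric oxide (-0.03 and 0.33) and NADPH oxidase lists (0.07 and -0.07), none of which passed. Cd34 stood at 6.88 ± 0.30 (SD, n = 3), Kit at 8.96 ± 0.17 and Ly6g at 5.80 ± 0.03 on the MDSC arrays.

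**Figure D3:**
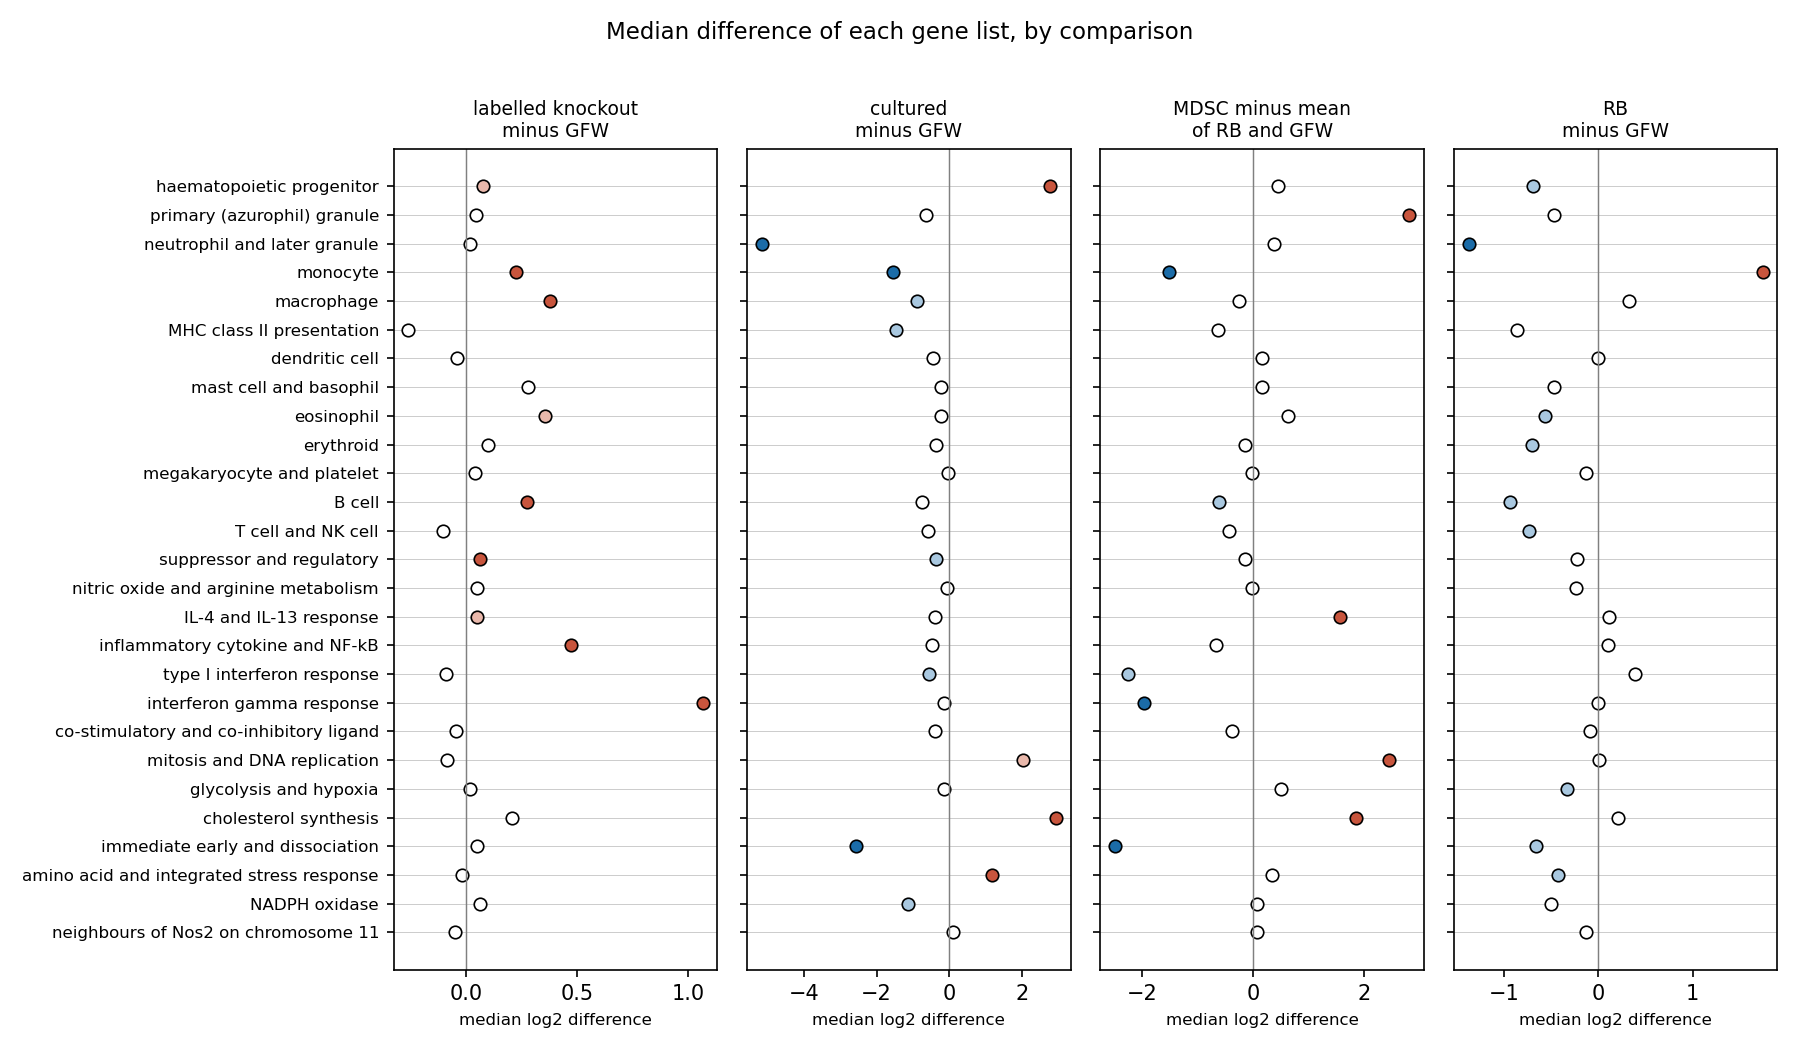
Median log2 difference of the 27 gene lists (y axis) in the 4 comparisons; red is higher and blue lower in the group written in front, dark where camera passes also with an estimated correlation, pale where it passes with the preset correlation alone, and white where it does not pass. The interferon gamma list lies at 1.06 in arrays labelled knockout minus GFW and at -1.98 in MDSC minus the mean of both wild-type sets.

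Against the mean of both sets 4595 genes were higher and 3730 lower in MDSC (1804 and 907 by at least 2-fold), and 3000 higher and 1862 lower genes passed against each set alone in the same direction. A further 247 genes were higher than RB and lower than GFW, and 329 lower than RB and higher than GFW. With each array minus its median the split was 3644 and 6402, so the share higher went from 55.2% to 36.3%, and the median of all genes moved from -0.03 to -0.22. With 1 mean of all 6 arrays 2461 genes were lower, and the calls of F13a1 (adjusted p = 0.106), Klf4 (0.427), Ly6g (0.0567), Kit (0.806) and Nos2 were lost. With the title prefix as a random block 1376 were higher and 726 lower. In that fit 9 of the 52 called genes followed lost their call, the 7 given above and Ly6g (0.0928) and Kit (0.887). Kit was lower than GFW (-2.47) and higher than RB, and its call against the mean of both (0.49 higher) was lost without MDSC replicate 3 (adjusted p = 0.0788). The MDSC arrays have a title prefix of their own, so a difference between runs cannot be told apart from the difference between cell types.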

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

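All tests of the 3 patterns weighed here were chosen after the result was seen, except the test on plasma cell genes and the counts of other splits.

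Against the 2 wild-type sets the MDSC arrays differed in opposite directions by median for 3 gene lists that also passed camera for RB minus GFW. Both conditions singled the lists out, so the camera p values of RB minus GFW given here are no separate test. Lists with opposite medians that did not pass are not counted. The progenitor list had a median of 0.79 in MDSC minus RB and -0.08 in MDSC minus GFW (mean 0.08 in the latter), and its RB minus GFW median was -0.69 (camera adjusted p = 0.0212, and 0.088 with an estimated correlation). The neutrophil and later granule list had 0.68 and -0.37, and -1.37 between the sets (1.29e-06 and 0.0136). The erythroid list had 0.21 and -0.29 (mean 0.16 in the latter), and -0.71 between the sets (0.0340 and 0.088).

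The RB and GFW arrays carry the same labels, yet 7760 genes differed. For a run difference that moves genes whatever their cell type, the gap between list medians was tested. The highest, of monocyte genes, lay 3.11 log2 above the lowest, of neutrophil genes. The widest such gap in 10000 random sets of 27 lists matched in signal level was 2.90 (permutation p = 1e-04 over genes, the smallest the permutations can give). Genes are not independent replicates, and the random lists lack the correlation of real list members, so the gap does not decide. Both lists also passed camera with an estimated correlation (adjusted p = 0.00254 and 0.0136). Title code and set are the same split, however, so a run difference stays open. For the addition of mature neutrophils to one monocyte population, which need not raise progenitor genes, 13 of 18 progenitor genes were lower in RB. Over all genes 3929 of 14822 were lower, and with an estimated correlation the adjusted p of the list was 0.088, so this stays open. It stays open for the monocyte genes too, whose spread of 6.35 log2 among the brightest members cannot be read without knowing which of them neutrophils express. The sort removed cells with Ly6G, yet Ly6g signal was higher on the GFW arrays. Whether the RB arrays hold a monocyte population with little Cd34 RNA stays open: Cd34 was lower there (-1.27, adjusted p = 7.19e-06), but that value was known when the test was chosen and supports nothing further. No biological difference between these sets is named by the labels, and none was tested.

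Nos2 was not lower on the arrays labelled iNOS knockout (0.61 log2 higher than GFW, adjusted p = 0.0125, lost without GFK replicate 3, 0.0539, or GFW replicate 1, 0.0587). An exchange of the GFK and GFW arrays would place the GFW arrays at the level of cells with little Nos2, and their mean lay 1.65 log2 above the highest of the RB, MDSC and cultured groups, but this decides only if the probe set reads the deleted exons alone. A probe set that reads exons left by the deletion could also give the value of 0.61. The explanations cannot be told apart, because the probe positions and the deleted exons are not known here.

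Interferon gamma and inflammatory genes were higher on the arrays labelled knockout, with B cell and macrophage genes beside them. Low values on the GFW arrays alone are hard to hold against a median of 1.41 over the interferon gamma list in arrays labelled knockout minus RB (11 of 13 called, camera adjusted p = 1.34e-05), but with an estimated correlation the p was 0.0600, so this stays open. For a larger share of macrophages, the interferon gamma median exceeded the macrophage median by 0.69 (permutation p = 5.4e-04 over genes, which are not independent replicates), but 13 of the 18 macrophage genes ranked at or above percentile 60 on the GFW arrays, where a small added share could be hidden, while Cd5l (1.66) and Marco (1.45) rose; this reading, which keeps the explanation open, was adopted after the result was seen. For plasma cells, which the sort for CD11b would remove, 10 genes not looked at before had a median of 0.0457 (Lman1 alone called, 0.94, and lost without GFK replicate 1 or 3 or GFW replicate 2 or 3, adjusted p up to 0.111), below the bound of 0.1 set in advance but not by more than their spread, and Sec11c, Slamf7, Ssr4 and Ell2 among them ranked at percentile 85.8 or above on the GFW arrays, so this too was left open after the result was seen, beside Jchain (1.12), Ighm (1.30) and Ighg3 (at least 2.47). A difference between the genotypes stays open and untested.

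With 3 arrays against 3, the 10 splits are too few for a share under 0.05. The real and the highest other counts of genes called were 239 and 3 for the arrays labelled knockout, 9931 and 0 for culture, and 7760 and 1 for RB against GFW. For MDSC against all 6 wild-type arrays as 1 group, 2 of 84 splits gave at least as many genes as the real 6093. A share of 2 in 84 treats the 9 arrays as exchangeable, but arrays of a title prefix correlated at 0.652 in a fit with 1 mean for RB and GFW. By whole title prefix these arrays have 3 arrangements, too few for a share under 0.05. This reading of the 84 splits was adopted after the result was seen, in place of a bound of 5% set in advance. The other of the 2, with 6540 genes, set the GFW arrays against the rest, a split that follows a title code and shows a structure of the samples, and the next had 2688. With the title prefix as a random block 1376 genes were higher and 726 lower.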

How the results depend on the processing

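Every alternative was fixed before the data were examined, and none was added later. Of the values followed per gene, 1027 of 1290 kept their side of the threshold without a reversal for the arrays labelled knockout (254 weaker, 3 stronger, 6 reversed). The counts were 1116 of 1134 for culture (11, 5 and 2), 1184 of 1218 for MDSC (26, 4 and 4) and 679 of 686 for RB minus GFW (7 weaker). Reversed means a change of direction in a gene called in the main fit or in the alternative. A gene called in neither counts as kept whatever its direction. Such genes were followed too: of 72 for the arrays labelled knockout, 56 were called in the main fit. Of the values per list, 132 of 162 kept direction and call for the arrays labelled knockout (29 weaker, 1 reversed). For culture, MDSC and RB minus GFW 203 of 216, 191 of 198 and 133 of 158 did, and the rest were weaker. Unless a construction is named, the cause was not tested.

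For the arrays labelled knockout, the genes higher and lower (192 and 47) were 72 and 2 with only the arrays compared. There the spread rests on fewer arrays and on GFK and GFW alone, and these changes were not told apart. The counts were 53 and 2 at 2-fold, 14 and 0 with treat (limma's test against 1.5-fold), and 49 and 13 with both sets as wild type. The lower genes were 30 with no filter, which tests more genes, 75 after quantile normalisation again and 79 with the variance trend and robust fit. With 1 array left out the counts ran from 102 to 150 and from 27 to 42. With both sets as wild type Tnfaip3 (-0.023), Cybb (-0.29), Ace (-1.48), Spn (-0.22), Nr4a1 (-0.20), Ifit1 (0.31) and the monocyte list (mean -0.76) reversed, and the macrophage (mean 0.097, adjusted p = 0.112) and IL-4 and IL-13 (0.326) calls ended, as RB enters the comparison. None of the reversed genes was called there (adjusted p from 0.448 to 0.982), nor was the monocyte list (0.0828).

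For culture, 2718 and 1324 genes passed at 2-fold and 2808 and 1425 with treat. The lower genes were 7694 with each array minus its median and 2979 with both sets as input. In the latter fit Kit (2.37, adjusted p = 0.166) and Sesn2 (0.35, 0.486) reversed and were not called. For MDSC, 1804 and 907 passed at 2-fold, 1956 and 1053 with treat, and 1376 and 726 with the title prefix as a random block (correlation 0.652). With that block the calls of Nos2, Egr2, Igsf6, Arg1, F13a1, Klf4, Cd22, Ly6g and Kit ended. For MDSC 6402 were lower with each array minus its median and 2461 with 1 mean of all 6 arrays. Against RB alone Nos2 (0.21) and Klf4 (-0.60) reversed, and against GFW alone F13a1 (0.065) and Kit (-2.47), as the sets differ. Of these Klf4 (adjusted p = 0.00431) and Kit (6.73e-09) were called, and Nos2 (0.160) and F13a1 (0.756) were not. For RB minus GFW, 1256 and 739 passed at 2-fold and 1198 and 727 with treat.

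The lists called were 6 for culture and 2 for RB minus GFW with an estimated correlation, 25, 25 and 19 for culture, MDSC and RB minus GFW with fry, which does not compare a list with other genes, and 4 and 6 for RB minus GFW with each array minus its median and after quantile normalisation again. The 2-fold and treat alternatives leave the list test untouched, and it was not run with the random block.

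With the replicate number as a block, 135 genes were higher and 14 lower on the arrays labelled knockout (10 lists called) and 5123 higher and 4703 lower after culture. This fit also left out the RB and MDSC arrays, so a change may come from the block or from the arrays left out. The calls of the progenitor list on the arrays labelled knockout (0.0668) and of the suppressor list after culture (0.0511) ended. So did those of Tcea2, Ftsj1, Mpc1, Plekho1, Hmox1, Maf, Hlf, Jchain and Ifit1 on the arrays labelled knockout (adjusted p from 0.0510 to 0.187). The labels do not say that the numbers pair the samples. After removal of group means, an array correlated with the GFW array of its own number at 0.016, 0.032 and 0.014 (GFK) and 0.035, 0.043 and -0.02 (cultured), none above 0.1, so the numbers were not taken as pairs. As a hint from the data in the other direction, the best match was the array of the same number for 3 of 3 GFK and 2 of 3 cultured arrays, all but cultured replicate 3. The floor of the signal limits dim genes, and 7358 genes were not tested. Small differences were often missed: of simulated shifts of 0.5 log2 in tested genes, 31.3% were called for the arrays labelled knockout.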

Other observations

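Cultured MDSC and mobilised cells after culture shared part of their difference from uncultured cells, in 2 comparisons with no array in common. Of 4057 genes higher in MDSC than in RB and 5198 higher after culture than in GFW, 2658 were the same genes, where independent lists would share 1423. Of the lower genes 1611 were shared (981 for independent lists), and 547 and 537 were called in opposite directions (1295 and 1078 for independent lists). Across the 14822 genes the differences correlated at r = 0.42, and genes are not independent replicates. Both comparisons took the spread of a gene from the same fit of all arrays, so their calls are not independent. The MDSC and RB arrays also differ in title prefix, so a difference between runs may enter MDSC minus RB. Cholesterol synthesis genes were higher and immediate early genes lower in both. Mitosis genes were called higher in both with the preset correlation, but after culture not with an estimated one (adjusted p = 0.0654). Against RB alone, MDSC also held more glycolysis transcripts (10 of 14 higher, adjusted over the list alone 10 higher and 1 lower, median 0.78, camera adjusted p = 0.00373, and 0.0316 with an estimated correlation), with Egln3 at least 2.95 (RB at percentile 38.5), Tpi1 1.66 and Pdk1 1.61, and more amino acid stress response transcripts (10 higher and 1 lower of 12, 11 and 1 adjusted over the list alone, median 0.86, 0.00234 and 0.0289), with Asns 2.62 and Psat1 2.11. Both lists were called lower in RB than in GFW with the preset correlation alone, and Egln3 was -3.12 there, a lower bound. These differences from RB therefore do not show that MDSC differed from GFW. The overlap, and which of the lists of MDSC minus RB are given here, were chosen after the values were seen.

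Of the antibody genes, Jchain and Ighm differed between groups of arrays, and these genes were chosen after their values were seen. Jchain, which joins IgM and IgA chains, stood at 9.57 on the arrays labelled knockout, 8.45 on GFW, 4.92 on RB and 4.18 on MDSC arrays, and Ighm at 13.02, 11.72, 10.63 and 9.38. The Jchain call on the arrays labelled knockout was lost without any array but GFW replicate 3 (adjusted p up to 0.138), the light chain gene Iglv1 was not called (6.39 against 6.13 on GFW, adjusted p = 0.869), and 10 plasma cell genes did not pass as a set. Of the B cell list 7 of 8 members were higher on the arrays labelled knockout than on RB (median 1.51, camera adjusted p = 5.79e-04, and 0.0361 with an estimated correlation). The list was also lower in RB than in GFW (mean -0.94, camera adjusted p = 0.088 with an estimated correlation). Part of the gap to RB therefore lies between the wild-type sets. Marco stood at 7.40 on the arrays labelled knockout and 7.56 after culture, against 5.94 on GFW and 5.46 on RB arrays.

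Xist lay between 10.26 and 12.13 on all 15 arrays, and the Y-linked genes Kdm5d, Eif2s3y and Uty between 3.49 and 4.48, so no array stood apart from the others by sex. Array pairs correlated at a median of 0.977 between GFW and the arrays labelled knockout, 0.87 between GFW and RB, 0.728 between GFW and the cultured cells, and 0.883 between the cultured cells and MDSC, against 0.975 to 0.99 within groups.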
